A study of Arabidopsis thaliana with 6 samples.

How the data were processed

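RNA from Arabidopsis thaliana siliques, the seed pods of the plant, was hybridised to 6 Affymetrix ATH1 arrays, 3 of young pods and 3 of old pods. The plants were of the accession Col-1 and grew in a glasshouse under continuous light, per the labels. The labels give the same tissue and developmental stage to all 6 samples, and only the titles separate young from old pods. How the age of a pod was set is not given in the sources used here. The titles number the replicates 1 to 3 in each group, and nothing in the labels says that they came from separate plants. The p-values therefore measure only the spread between these samples. The number of arrays limits the precision.

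The deposited values are intensities, 1 signal per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version and the detection calls are not given in the sources used here. The mean after trimming 2% from each end was about 100 on every array, so each array had been scaled to the same target before deposit. This scaling fixes the average of each array, so a change that ran through most transcripts would not be visible in these values.

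The array holds 22810 probe sets, of which 64 are controls. Of the other 22746, the platform annotation table names 1 gene for 13513, several genes for 503 and none for 8730. Of those naming 1 gene, 1580 carry a symbol and 11933 only a locus tag. Names were checked by gene number against the TAIR10.1 reference, which held 13436 of the 13513. Probe sets with several genes or none entered the tests and the counts without a name. Where several probe sets named a gene, the 1 with the highest mean log2 signal was used.

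Signals were taken as log2, with signals under 0.1 set to 0.1 first. A probe set was tested when its signal lay above the array's 40th percentile on at least 3 of the 6 arrays. Old and young pods were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the mean), with no further normalization. Adjusted p-values are from the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05, and all tests were two-sided. Fold changes are old against young pods, with standard errors (SE) on the log2 scale. A probe set under the percentile on all arrays of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean log2 signal against the dimmer group's mean of the higher of the percentile and its own signal. Data were simulated in 5 runs with the measured means and spread of the 14277 tested probe sets, 200 of them changed. There the comparison of old with young pods recovered 13.2% of 2-fold changes and 64% of 4-fold changes, and 4.46% of its calls were false. Far more probe sets passed in the real comparison, which loosens the adjusted threshold, so these shares need not hold for it.

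The gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be later. There were 32 such lists, for senescence, photosynthesis, hormones, cell walls, seeds and other tissues that a pod could hold. Of their 623 members, 104 had a named probe set and 86 were tested. A list was tested with at least 5 tested members, which left 6. A further 47 lists were made from the symbols in the annotation after the probe names had been seen and before their values were examined, and 42 of them were tested. Lists were tested with camera at a preset correlation of 0.01, against all other tested genes and the unnamed probe sets. Adjustment ran over the 6 and the 42 lists separately. Camera with an estimated correlation and fry were alternatives. Estimating the correlation leaves camera with far fewer degrees of freedom on 6 arrays, so its p can rise without a high correlation. No list of cytosolic ribosomal proteins was made, since the reference table gives no product names.

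The rule for named genes took 16 genes whatever their values, of which WRKY53 and ADPG1 had a named probe set. It took the 10 largest rises and 10 largest falls among genes with a symbol that passed the threshold, whose groups did not overlap and that were measured in both groups. It took the 5 largest bounds in each direction, and up to 4 called members of each list or the 2 brightest where none passed. Some list members that did not pass, SAG29, GTR1 and OLEO3 among them, are also named though they lie outside the rule. They were not recomputed as single genes under the alternatives.

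RNA quality was read from the log2 ratio of 3 prime to 5 prime probe sets of 3 control transcripts, compared by an exact permutation test. Over the tested probe sets, the arrays of 1 group correlated at 0.858 to 0.951 and arrays of different groups at 0.580 to 0.693, and no 2 arrays were identical. Deviations from the group means correlated at 0.286, 0.113 and 0.119 between the young and old arrays with replicate number 1, 2 and 3. All 3 were above 0.1, the cut used here for pairing by number. Young replicate 2 with old replicate 3 gave 0.187, and young replicate 3 with old replicate 2 gave 0.114. The values therefore set the replicate 1 pair apart, but do not single out pairs among replicates 2 and 3. Any pairing comes from these values and not from the labels. The first principal component of the deviations, with 49% of the variance, set both replicate 1 arrays apart. The hybridisation controls, bacterial transcripts added to each sample, also set these arrays apart, with mean signals of 871 and 998.4 against 262.7 to 388.5 on the other 4. Replicate 1 was therefore read as a technical batch that holds both groups, though the main fit has no term for it. Fits of replicates 2 and 3 alone, a batch term, the replicate 1 pair without a test, and bounds without 1 array were added after seeing the data.

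The alternatives fixed in advance were 5 scalings, no filter and a filter at the 60th percentile, a floor, an offset, other variance models, the replicate number as a block, leaving out each array, means over a gene's probe sets, and leaving out probe sets with ambiguous suffixes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.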

Results

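The series was made to find changes in transcript levels as Arabidopsis siliques senesce. Siliques are pods whose 2 valves enclose the seeds and open along a dehiscence zone. Transcripts were measured on 6 arrays, 3 of young pods and 3 of old pods. The median signal was 52.9, 49.5 and 51.8 on the young arrays and 49.6, 40.3 and 39.5 on the old arrays.

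The rankings here hold only among genes with a symbol whose groups did not overlap. Of the 3145 probe sets past the threshold, 299 named 1 gene with a symbol. The largest such rise with both groups measured was in CHI (locus AT2G43570, a chitinase gene and not the chalcone isomerase of the same abbreviation). CHI was 41.6-fold higher in old pods (log2 fold change 5.38, SE 0.36, n = 3 arrays per group, limma adjusted p = 0.000268). ADPG1, a polygalacturonase of the dehiscence zone, rose 15.7-fold, from a mean signal of 70.7 to 1108 (SE 0.31, limma adjusted p = 0.000387). SBT3.5, a subtilisin-like protease, rose 17.8-fold with an SE of 0.191. BCAT4, an aminotransferase of methionine chain elongation in glucosinolate synthesis, rose 10.3-fold, and MSRB5, a methionine sulfoxide reductase, rose 9.15-fold. AtLEA4-1, a late embryogenesis abundant protein, rose 11.1-fold. CYP78A9, a cytochrome P450 that acts in fruit growth, rose 7.16-fold, the cell wall invertase family member cwINV6 rose 6.31-fold and the carboxypeptidase-like gene scpl46 rose 6.21-fold. UGT76E12, a glycosyltransferase, rose 13.3-fold on a young spread of 1.97 (SD, log2, n = 3 arrays), and its call ended without young replicate 2, old replicate 2 or old replicate 3 (limma adjusted p up to 0.0674). Its rise was 25.9-fold without young replicate 1 and 6.62-fold without young replicate 3. With signals under the percentile raised to it, the rise was 37.4-fold for CHI, 6.01-fold for AtLEA4-1, 7.48-fold for UGT76E12 and 4.4-fold for scpl46. For the 5 largest bounds among the rises, all young arrays were under the percentile. PAP85, a vicilin-like seed storage protein, rose at least 16.1-fold (at least 6.21-fold without old replicate 1, and at least 25.8-fold and 26.1-fold without old replicates 2 and 3), CYP71B23 at least 12.8-fold, UGT87A2 at least 9.52-fold, the methyltransferase CCOAMT (locus AT1G67980) at least 7.31-fold and CYP71B24 at least 6.47-fold.

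Among genes with a symbol, the deepest falls in old pods included genes of flavonoid synthesis and of the seed coat. BAN, the anthocyanidin reductase of proanthocyanidin synthesis in the seed coat, fell from a mean signal of 1797 to 16.0, which is 112-fold (log2 fold change -6.81, SE 0.62, n = 3 arrays per group, limma adjusted p = 0.00057). Old replicates 2 and 3 were under the percentile for BAN, and with their signals raised to it the fall was 58.7-fold. DFR, the dihydroflavonol reductase before it in the pathway, was 27.5-fold lower, and DELTA-VPE, a vacuolar processing enzyme of the seed coat, was 45.5-fold lower. CHIL, a chalcone isomerase-like gene, was at least 35.9-fold lower and the flavonol glycosyltransferase UGT78D1 at least 8.51-fold lower, with all old arrays under the percentile. GILT, named for a thiol reductase, had the largest fall among genes with a symbol and both groups measured. Its fall was 134-fold, from 6239 to 46.6, or 108-fold with signals raised to the percentile. The GILT fall was 282-fold without old replicate 1 and 71-fold without old replicate 2. Without old replicate 1 the fall was 192-fold for BAN, 78.7-fold for DELTA-VPE and 42.1-fold for DFR. The endoglucanase GH9C1 fell 9.61-fold and TBL45, of a family of wall polysaccharide acetyltransferases, 11.7-fold (9.46-fold with signals raised to the percentile). The subtilase SBT1.3 fell 12-fold, LSH5 12.4-fold, the defensin-like gene LCR69 10.3-fold and the purple acid phosphatase gene PAP20 10.1-fold (6.31-fold with signals raised to the percentile). The fall of SBT1.3 was 7.82-fold without young replicate 3 and that of PAP20 15.7-fold without old replicate 1. The wax ester synthase WSD1 was at least 8.14-fold lower, the chromatin remodelling gene chr31 at least 8.12-fold and the thionin THI2.1 at least 7.35-fold (at least 4.61-fold without young replicate 3).

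**Figure D1:**
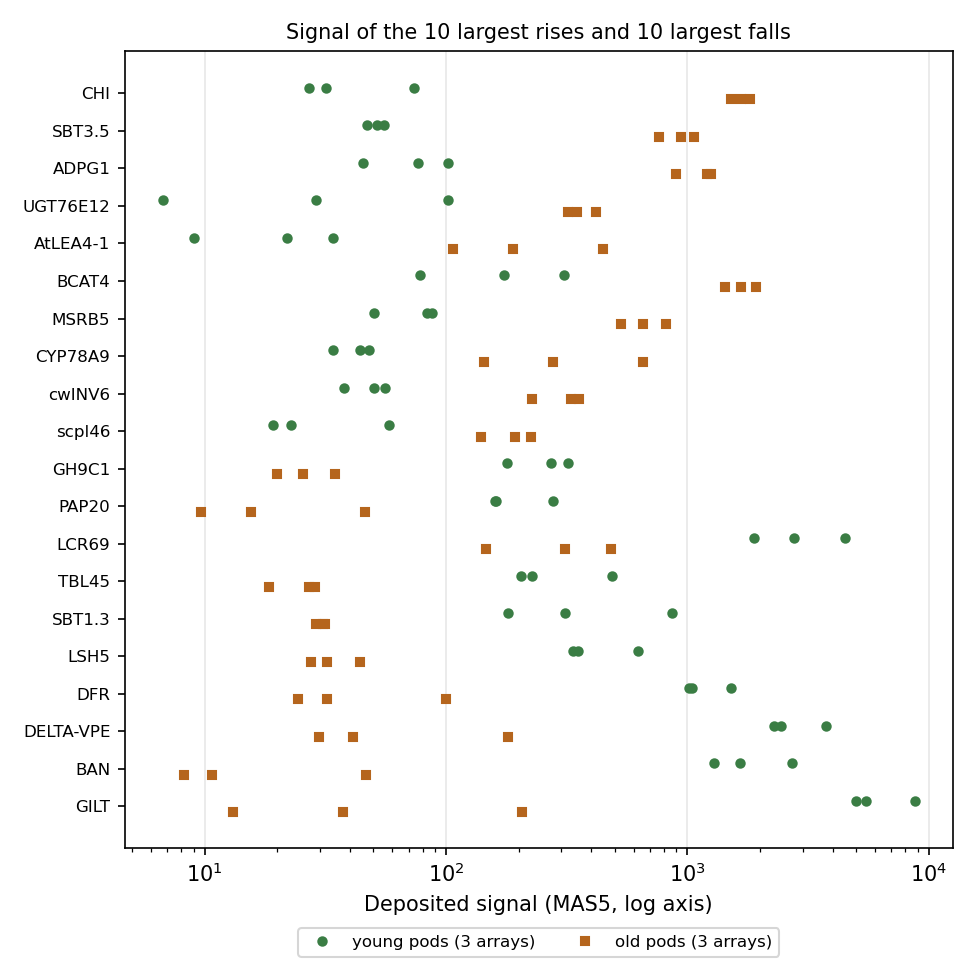
Signal on each array (log axis, arbitrary MAS5 units) of the 10 largest rises and 10 largest falls among genes with a symbol, measured in both groups. Genes with only a bound in a group are not drawn. Each circle is 1 of 3 young arrays and each square 1 of 3 old arrays. The groups do not overlap for any of these genes, by the rule that chose them.

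In all, 3145 of the 14277 probe sets tested differed between old and young pods, 1382 higher and 1763 lower in old pods, and by at least 2-fold 1004 were higher and 1402 lower. Among the 3145, 674 of the higher and 850 of the lower probe sets named 1 gene, and 1558 were not named. The signals of the groups did not overlap for 40.9% of the tested probe sets, against 10% by chance. All young arrays were under the percentile for 261 of the higher probe sets, and all old arrays for 356 of the lower. Replicates 2 and 3 alone gave 3936 probe sets, and the batch term for replicate 1 gave 4197. The replicate 1 pair allows no test, and 92.5% of the 3936 moved the same way in it. Scaling on the hybridisation controls gave 607, of which 570 were among the 3145. It sets the replicate 1 arrays apart inside each group, while the log2 fold changes moved by a median of only -0.0683. This scaling ended the calls of cwINV6 and scpl46 (adjusted p = 0.0721 and 0.0537). It also ended those of every list member named below that had passed, apart from EXPA8 and the genes already named above. For these list members the adjusted p was at least 0.0912, with 0.247 for WRKY53, 0.197 for PSAN, 0.815 for PSAE-1 and 0.294 for AMY1. The two-sample test without moderation ended 36 of the 93 calls of named genes, among them PAP85 (adjusted p = 0.11) and UGT76E12 (adjusted p = 0.123). Without old replicate 2, young replicate 2, young replicate 3 or old replicate 3 the count was 1736, 1812, 1975 or 2047.

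Of the 5 tested members of the list of senescence regulators and markers, 3 rose and none fell, and 3 passed adjusted over the list alone. WRKY53, a transcription factor that promotes leaf senescence, rose 4.73-fold (SE 0.249, limma adjusted p = 0.00118), and WRKY6 and SAG101, both under the percentile in young pods, rose at least 3.42-fold and at least 1.55-fold. The calls of WRKY6 and SAG101 ended without old replicate 2 (WRKY6 also without old replicate 3, SAG101 without young replicate 2), with adjusted p up to 0.0614 and 0.0811. With low signals raised to the percentile, SAG101 did not pass (adjusted p = 0.0901). WRKY6 was at a log2 change of 0.811 in the replicate 1 pair and at 2.641 in replicates 2 and 3. The ordinary two-sample test also ended the WRKY6 call (adjusted p = 0.0937). SAG29 and WRKY22 did not pass, at 0.13 and -0.12. The list's median log2 fold change was 1.42, with 1.00 in the replicate 1 pair and 1.28 in replicates 2 and 3. With WRKY6 and SAG101 at their bounds it was 0.63. The list had a camera adjusted p = 0.0165, and adjusted p = 0.185 with an estimated correlation. That estimate was -0.135, under the preset 0.01, so for this list correlation between the members does not account for the higher p. For the photosystem and antenna, autophagy and glucosinolate lists below, the estimates were 0.388, 0.387 and 0.303, all above the preset. Correlation is left open there.

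Among 7 tested photosystem and antenna proteins 5 fell and none rose, and 6 fell adjusted over the list alone. PSAN, a photosystem I subunit, fell 4.67-fold (SE 0.36), and PSAE-1, another, fell 2.25-fold (SE 0.218). The antenna protein LHCB4.2 fell 3.87-fold, a call that ended without replicate 2 or 3 of either group (limma adjusted p up to 0.0864), with a log2 change of -2.56 without young replicate 1. ATPC1, a subunit of the plastid ATP synthase, fell 1.72-fold. Its call ended without replicate 1 or 2 of either group or old replicate 3 (adjusted p up to 0.125), in replicates 2 and 3 alone (0.118), and with median centring, reference gene scaling or no filter (0.064, 0.0775 and 0.0785). The list's median was -0.78 (-0.77 in the replicate 1 pair, -0.78 in replicates 2 and 3), with a camera adjusted p = 0.00175 and an adjusted p = 0.267 with an estimated correlation. Of 7 chlorophyll synthesis genes, CHLI2, a magnesium chelatase subunit, and CHLM, the methyltransferase after it, fell 2.51-fold and 2.03-fold. The list did not pass, with a median of -0.46 (-0.15 in the replicate 1 pair, -0.64 in replicates 2 and 3) and a camera adjusted p = 0.213, or adjusted p = 0.685 with an estimated correlation. The CHLI2 call ended without young replicate 2 (adjusted p = 0.0533) and the CHLM call without old replicate 1 or replicate 2 or 3 of either group (up to 0.145). The CHLM call also ended with median centring, reference gene scaling, no filter or no variance trend (adjusted p 0.0519 to 0.0688). In carbon fixation, SBPASE, a Calvin cycle phosphatase, fell 2.51-fold, and PRK and RCA did not pass, at -0.56 and -0.36. Both tested chlorophyll breakdown genes missed the threshold, NOL at -0.53 and the locus AT1G44000 at -0.79. NOL was at -1.555 in the replicate 1 pair and at -0.014 in replicates 2 and 3. AT1G44000 passed with the replicate number as a block (adjusted p = 0.0224) and adjusted over the list alone.

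Of 11 tested autophagy genes, most of them of the ATG8 family of autophagosome proteins, 4 rose, none fell and 6 rose adjusted over the list alone. APG8A rose 2.00-fold (SE 0.209), ATG8B 1.82-fold and APG8H (locus AT3G15580) 1.72-fold, and ATG8E was higher by 1.09 on the log2 scale. The APG8A call ended without old replicate 2 (limma adjusted p = 0.0557), and each of the other calls ended without replicate 2 or 3 of either group, that of APG8H also without old replicate 1 and those of ATG8B and ATG8E also without young replicate 1 (adjusted p up to 0.155). Without the variance trend these 3 calls ended too (0.0592 to 0.0681), and with reference gene scaling or no filter those of ATG8E and APG8H (0.0527 to 0.0663), and that of APG8H after quantile normalization (0.0701). The median was 0.57 (0.34 in the replicate 1 pair, 0.62 in replicates 2 and 3), with a camera adjusted p = 0.00175 and an adjusted p = 0.281 with an estimated correlation. Scaling on the hybridisation controls ended this call (adjusted p = 0.103). Glucosinolate genes had the lowest camera value of the 6 lists, adjusted p = 0.00104, and an adjusted p = 0.185 with an estimated correlation. In this list 4 of 5 genes rose, adjusted over the list alone as well: BCAT4, the glycosyltransferase UGT74B1 (2.38-fold), the transporter GTR2 (2.31-fold) and the locus AT2G31790 (1.99-fold). The fifth, GTR1, did not pass at 0.33. The median was 1.21, with 1.008 in the replicate 1 pair and 1.16 in replicates 2 and 3. Cell death proteases and nucleases did not pass as a list (camera adjusted p = 0.823). DELTA-VPE was the only 1 of its 7 members past the threshold, and the median was -0.33 (0.007 in the replicate 1 pair, -0.47 in replicates 2 and 3).

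**Figure D2:**
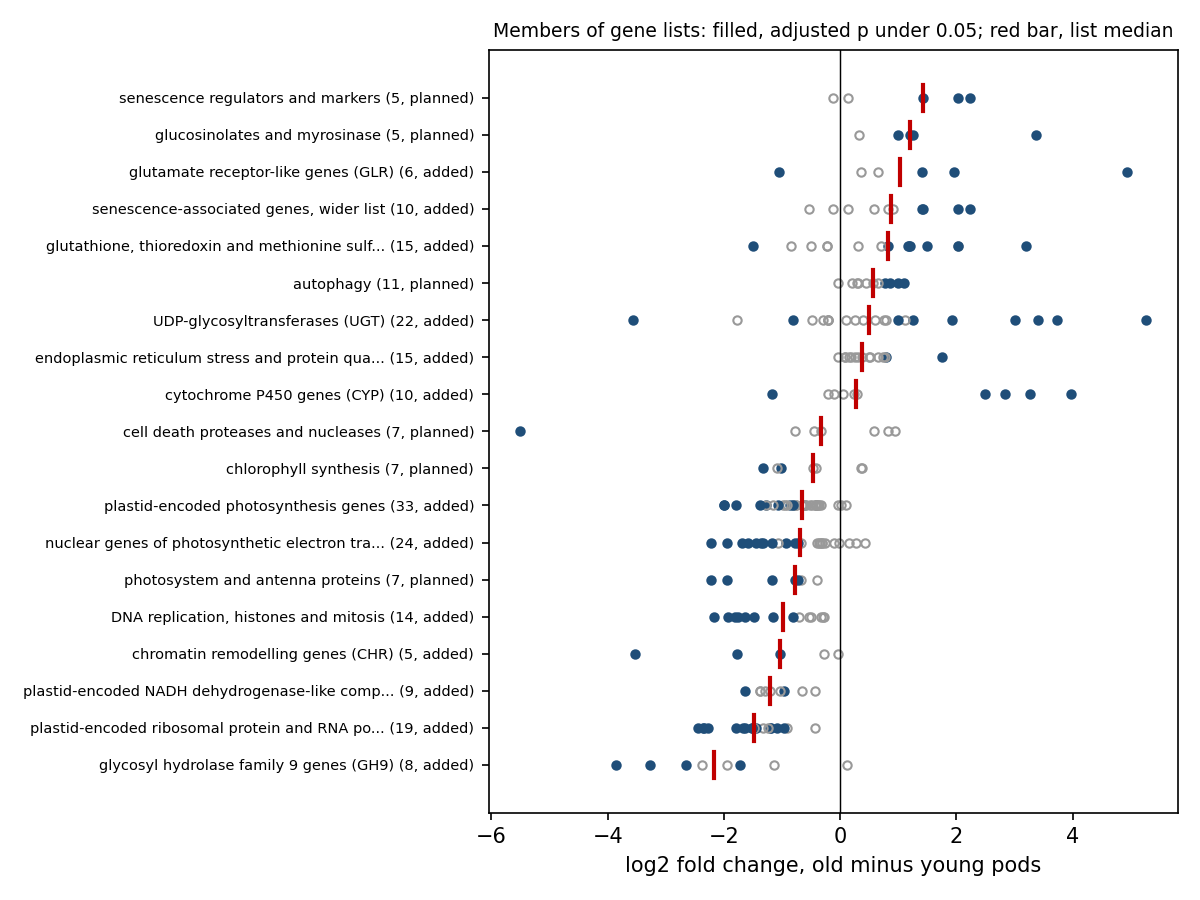
log2 fold change (old minus young) of each tested member of the 6 lists set in advance (planned) and the 13 later lists that passed (added), with the number of members in brackets; filled points are past the threshold, red bars are list medians, and genes with only a bound are drawn at their fitted value. Glycosyl hydrolase family 9 has the lowest median, at -2.16.

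The other 26 lists set in advance had fewer than 5 tested members and were not tested as lists. All 3 cell division genes fell: PRL, a replication licensing factor, 3.49-fold, the mitotic kinase AUR2 at least 1.84-fold and the mitotic kinase AUR1 1.75-fold. The AUR2 call ended without young replicate 2 and the AUR1 call without replicate 2 or 3 of either group (adjusted p 0.0779 and 0.0882 at most), and AUR1 did not pass with reference gene scaling (adjusted p = 0.0622). Both secondary wall genes fell, the xylan synthesis gene GUT2 3.94-fold and HCT of lignin synthesis 2.22-fold. A later list of 11 secondary wall, lignin and monolignol genes that holds both was mixed: 2 rose, CCOAMT among them, and 5 fell, and the list did not pass (median -0.485, -0.62 in the replicate 1 pair and -0.42 in replicates 2 and 3, camera adjusted p = 0.553). In sugar and starch metabolism AMY1, an alpha-amylase, rose 4.59-fold, SBE2.2, a starch branching enzyme, fell 5.33-fold, DPE1, a plastid glucanotransferase, fell 4.02-fold, and SWEET11 did not pass at 0.38. Of the flavonoid genes DFR and UGT78D1 fell and UGT78D2 did not pass, at 0.10. SDP1, the lipase that starts oil breakdown, rose 2.05-fold beside AIM1 at 0.11, and glutathione reductase GR1 rose 2.24-fold, a call that ended without young replicate 2, old replicate 2 or old replicate 3 (adjusted p up to 0.0569). In the valve margin list ADPG1 rose, and SPT and ALC did not pass at 0.27 and -0.24. Among hormone lists, OPCL1 of jasmonate synthesis rose 2.34-fold and THI2.1 fell. JMT, a jasmonate methyltransferase, was at -4.48 with an SE of 1.58 and overlapping groups, and passed adjusted over the list alone but not over all probe sets (limma adjusted p = 0.0799). The abscisic acid responsive COR15A fell at least 1.83-fold. EIN3 of ethylene signalling and ARR15 of cytokinin signalling did not pass (limma adjusted p = 0.0608 and 0.0562). Both passed with the batch term (adjusted p = 0.0416 and 0.03) and in replicates 2 and 3 (0.0482 and 0.0429). With the replicate number as a block neither passed (adjusted p = 0.0693 and 0.0599). EIN3, ARR15 and PPDK of the nitrogen list passed adjusted over the list alone, where each was the only member tested. The OPCL1 call ended without young replicate 2, old replicate 2 or old replicate 3 (adjusted p up to 0.127), after quantile normalization, without the variance trend and in the two-sample test (0.0615, 0.0566 and 0.158), its log2 change was 0.81 without young replicate 3, and the COR15A call ended without young replicate 3 (adjusted p = 0.0686). The expansin EXPA8 fell 7.25-fold in a list of 4 cell wall expansion genes, though its groups overlapped, with a call that ended without old replicate 1, replicate 2 of either group or young replicate 3 (adjusted p up to 0.133) and a log2 change of -3.73 without young replicate 1. For EXPA8 old replicates 1 and 2 and young replicate 1 were under the percentile. With signals raised to it the change was -1.83 and did not pass (adjusted p = 0.0501), nor did it pass after quantile normalization or in the ordinary two-sample test (adjusted p = 0.0818 and 0.171). Adjusted over the list alone, 1 of the 4 rose and 1 fell. PPDK, and FATB of the wax list, did not pass over all probe sets, at 0.92 and -0.11. PPDK was at 0.059 in the replicate 1 pair and at 1.346 in replicates 2 and 3, where it passed (adjusted p = 0.0137). It did not pass with the batch term (adjusted p = 0.067). None of the 3 reference genes passed, at -0.28 for PEX4, 0.52 for AT4G34270 and -0.42 for AT2G28390. The lists for salicylic acid and defence, heat shock and petals had no member with a named probe set, so their genes were not assessed. Those for pollen and roots had 3 and 1 members with a named probe set, none bright enough to be tested.

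Seed genes moved in different directions. PAP85 rose, BAN fell, and the other 4 tested members of the lists for seed storage, seed maturation, endosperm and seed coat did not pass. The oleosin OLEO3 was at 0.05 (SE 1.00), the regulators EEL and BZIP53 at 0.94 and 0.14, and the endosperm gene AGL80 at -0.14. The old arrays differed widely among themselves in these genes. PAP85 had a signal of 3700.8 on old replicate 1 and of 214.9 and 210.1 on the others, and OLEO3 had 2218.5 against 178.7 and 262.6. Without old replicate 1, the EEL value turned to -0.27.

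**Figure D3:**
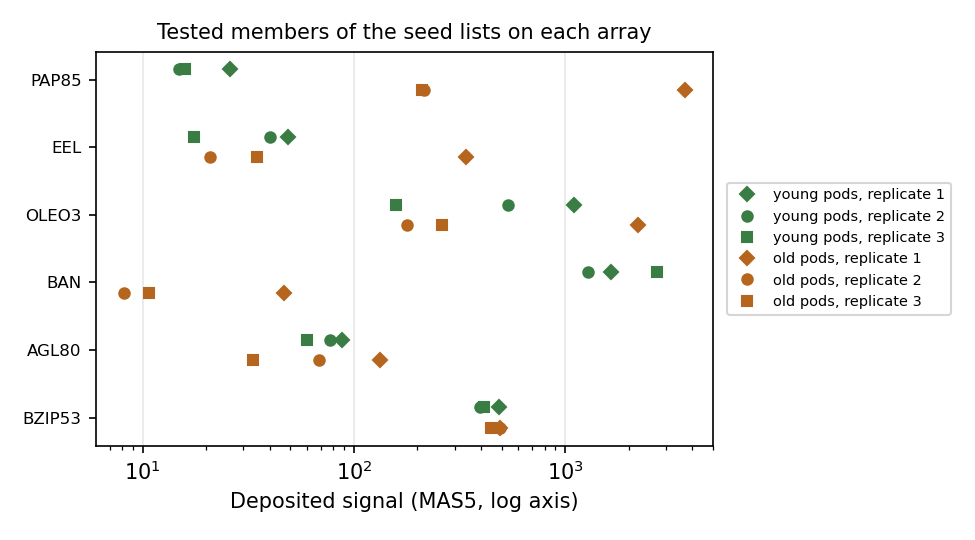
Signal on each array (log axis, arbitrary MAS5 units) of the 6 tested members of the seed lists; colour marks young or old pods and the symbol marks the replicate number. PAP85 is at 3700.8 on old replicate 1 and at 214.9 and 210.1 on the other old arrays.

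The log2 ratio of 3 prime to 5 prime signal of control transcripts, a sign of RNA breakdown, was 2.71 ± 0.38 in young pods and 2.85 ± 0.57 in old pods (SD, n = 3 arrays per group), a difference of 0.136 with an exact permutation p = 0.8. For actin the difference was 0.42, with every old array above every young array (exact permutation p = 0.1, the smallest this design allows). GAPDH and ubiquitin differed by 0.028 and -0.041 (exact permutation p = 1 for each).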

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

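The batch fits were chosen after seeing the data; the other settings were set in advance. The limits are the number of arrays and the dimness of many probe sets. Scaling on the hybridisation controls gave 232 higher and 375 lower probe sets, 607 in all, each by at least 2-fold (232 and 375). The controls were brighter on both replicate 1 arrays, so this scaling adds a replicate 1 deviation to every probe set inside each group. The log2 fold changes themselves moved by a median of only -0.0683. Whether the added spread alone accounts for the lost calls was not tested. The ordinary two-sample test without moderation gave 607 higher and 753 lower, 1360 in all, and 450 and 568 by at least 2-fold; its per-probe-set variance rests on few arrays. The other settings on all 6 arrays stayed within 1.5 times of the counts, and replicates 2 and 3 alone did so too. Leaving out 1 array at a time gave 1736 to 3602 probe sets in all, 720 to 1473 higher and 932 to 2129 lower, and by at least 2-fold 663 to 1104 higher and 894 to 1784 lower, with fewer arrays in each fit. Of the 93 named genes past the threshold, the hybridisation control scaling took 60 under it and the two-sample test 36, and each other setting on all 6 arrays at most 6. With the replicate block there were 3480 probe sets, of which 2955 were also called without it; it took 1 named gene (TUA1, adjusted p = 0.0642) under the threshold and added AT1G44000. Quantile normalization moved the median of all tested probe sets from -0.0825 to 0.01, and the share of calls that were higher lay between 38.2% and 52.1% over the 5 scalings, against 43.9%.

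Of the lists set in advance 4 passed under most settings, 3 with the hybridisation control scaling or the stricter filter, 5 with no filter, and 0 with an estimated correlation, where 0 also had an unadjusted camera p under 0.05; fry called 4. The replicate block changed no call among these lists; among the later ones it ended those of the glycosyltransferases, chromatin remodelling genes and glutamate receptors and added that of the tubulins. The 3 prime to 5 prime difference was 0.42 for actin, 0.028 for GAPDH and -0.041 for ubiquitin, where the sign turned. The median of the cell death list turned to 0.58 under the stricter filter, which keeps fewer genes, lay between -0.67 and 0.001 without 1 array, and was 0.007 in the replicate 1 pair. EEL ranged from -0.27 to 1.74 and FATB from -0.31 to 0.18 without 1 array. AGL80 was at 0.087 after quantile normalization, from -0.63 to 0.37 without 1 array and at 0.591 in the replicate 1 pair. The cause was not tested. The cell death list, EEL, FATB and AGL80 did not pass the threshold with all arrays. Of the 93 named genes, 66 passed it without each array in turn and 27 did not.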

Other observations

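The tests of the seed genes and of the plastid genes below were chosen after their values had been seen, and the lists here were made after the probe names had been seen. Of 19 tested plastid genes for ribosomal proteins and RNA polymerase, 14 fell and none rose, with a median log2 fold change of -1.48 (-1.39 in the replicate 1 pair, -1.56 in replicates 2 and 3, camera adjusted p = 3.13e-06, adjusted p = 0.454 with an estimated correlation). Among them rpoA fell by 2.35 and rpl36 by 2.45 on the log2 scale. Of 33 plastid photosynthesis genes 8 fell, with a median of -0.66 (-0.84 in the replicate 1 pair, -0.56 in replicates 2 and 3, camera adjusted p = 0.000612, adjusted p = 0.543 with an estimated correlation), and atpH, a subunit of the plastid ATP synthase, fell by 2.00. Of 9 genes of the plastid NADH dehydrogenase-like complex 2 fell, with a median of -1.21 (-1.47 in the replicate 1 pair, -1.08 in replicates 2 and 3), a camera adjusted p = 0.0119 and an adjusted p = 0.529 with an estimated correlation, and the list's call ended without old replicate 1 (adjusted p = 0.0538). Nuclear genes for photosynthetic electron transport went the same way. There 11 of 24 fell and none rose (median -0.69, -0.68 in the replicate 1 pair and -0.68 in replicates 2 and 3, camera adjusted p = 0.00167, adjusted p = 0.529 with an estimated correlation), among them NdhL at -1.70 and TROL at -1.58. Genes of DNA replication, histones and mitosis fell in 8 of 14 cases (median -0.99, -0.82 in the replicate 1 pair, -1.10 in replicates 2 and 3 and -0.78 with bounded genes at their bounds, camera adjusted p = 0.000292, adjusted p = 0.454 with an estimated correlation), including the histone gene HTB2 at -2.17 and the cell cycle inhibitor SIM at -1.75.

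Genes of glutathione, thioredoxin and methionine sulfoxide repair rose in 7 of 15 cases, while 1 fell (median 0.83, 0.54 in the replicate 1 pair and 0.93 in replicates 2 and 3, camera adjusted p = 0.0163, adjusted p = 0.454 with an estimated correlation). GRX480, a glutaredoxin, rose by 2.03 and MSRB5 by 3.19 on the log2 scale, and TAPX, a thylakoid ascorbate peroxidase, fell by 1.49. Of 15 genes of endoplasmic reticulum quality control, ATERDJ3B, a chaperone of the lumen, rose by 1.75, and OS9 was the other that rose (list median 0.38, 0.26 in the replicate 1 pair, 0.39 in replicates 2 and 3, camera adjusted p = 0.0119). The call of OS9 ended without young replicate 1 or replicate 2 or 3 of either group (adjusted p up to 0.076), and that of the list under hybridisation control scaling (adjusted p = 0.199; 0.454 with an estimated correlation). Among 8 glycosyl hydrolase family 9 genes, which encode endoglucanases, 4 fell and none rose (median -2.16, -1.50 in the replicate 1 pair and -2.93 in replicates 2 and 3, camera adjusted p = 0.00225, adjusted p = 0.454 with an estimated correlation). Of 10 cytochrome P450 genes 4 rose and 1 fell, with CYP71B6 at 2.49 and a list median of 0.27 (0.44 in the replicate 1 pair, 0.23 in replicates 2 and 3). The list's call (camera adjusted p = 0.0199) ended without old replicate 1 (adjusted p = 0.0506; 0.454 with an estimated correlation). In the wider senescence list 4 of 10 genes rose and none fell, YLS5 among them at 1.41, with a median of 0.87 (0.57 in the replicate 1 pair, 1.19 in replicates 2 and 3, and 0.72 with bounded genes at their bounds) and a camera adjusted p = 0.00799, and lost its call under the stricter filter (adjusted p = 0.055; 0.454 with an estimated correlation). The calls of the glycosyltransferases (7 rose and 2 fell of 22), glutamate receptor-like genes (3 rose and 1 fell of 6) and chromatin remodelling genes (3 fell of 5) ended with the replicate block, at adjusted p 0.0586, 0.05 and 0.0586 against a camera adjusted p = 0.0373 for each without it and 0.454 for each with an estimated correlation. Without 1 array they also ended, for the glycosyltransferases without old replicate 1, young replicate 3 or old replicate 3 (adjusted p up to 0.0637), for the glutamate receptors without old replicate 1, 2 or 3 (up to 0.0603) and for the chromatin genes without replicate 1 of either group or old replicate 3 (up to 0.0687). Their medians were 0.49, 1.025 and -1.04, with 0.036, 0.80 and -0.92 in the replicate 1 pair and 0.63, 1.15 and -1.09 in replicates 2 and 3. With bounded genes at their bounds the first was 0.45 and the second 0.64. Of the genes named so far in this part, hybridisation control scaling ended every call but that of MSRB5 (adjusted p 0.0912 to 1). Of the 42 lists tested, 29 did not pass. With an estimated correlation in camera 0 of the 42 passed, 2 had an unadjusted camera p under 0.05, and fry called 22. The estimate was 0.408 for the plastid ribosomal protein and RNA polymerase list but -0.0253 for the endoplasmic reticulum list. Correlation therefore does not account for every lost call.

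The fall of plastid transcripts was set against 2 technical explanations. All 61 tested plastid genes had a median of -0.98 (-1.13 in the replicate 1 pair, -0.96 in replicates 2 and 3), and 24 fell and none rose. Plastid RNA mostly lacks long poly(A) tails, so weaker priming of such RNA in old pods could lower it. This is argued against by the mitochondrial transcripts, which also lack them, provided that their own levels did not rise with age. The 12 tested mitochondrial genes had a median of 0.434 with an SD of 0.63 across genes. Their median was 0.61 in the replicate 1 pair and 0.17 in replicates 2 and 3. Whether weaker priming was masked by a rise in their levels was not tested. The 25S ribosomal RNA signal, which varied widely within each group, differed by 1.33 on the log2 scale toward old pods. The authors' scaling is argued against only for a fall relative to the other tested transcripts. Under 5 other scalings the plastid median was no closer to 0 than -0.885. These scalings moved the log2 fold changes by a median of 0.1 at most, so they cannot decide on a fall in absolute amount. A change in the age or tissue make-up of the pods was not tested, and the RNA quality values above leave breakdown open, since 3 arrays a group allow no exact p under 0.1.

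On old replicate 1 the 6 tested seed list members were all brighter than on the other old arrays, by a median of 2.84 on the log2 scale, whereas 39.1% of all tested probe sets were brighter there than on both others. The median was 0.57 on young replicate 1 against the other young arrays. The difference of these deviations had a median of 1.969 and an SD of 1.303 across the 6 genes, but a median of 1.268 and an SD of 1.52 with signals under the percentile raised to it. A batch effect of the same size in both groups and a difference between the pods of that array therefore cannot be told apart, since several of these signals lie under the percentile and the spread of the genes exceeds their median. BZIP53 deviated by only 0.067 in old pods. A larger share of seed RNA, or seeds of another stage, may be behind the values of that array; this is a hypothesis, since it was raised by these genes and was not tested on others. The rise of PAP85 did not need that array: in replicates 2 and 3 alone it was at least 6.42-fold (limma adjusted p = 0.000132).

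Of the 10 ways to divide the 6 arrays into 3 and 3, 1 gave as many probe sets as young against old pods. That was the real division, with 3145, and the highest of the others gave 0. Each of the others puts both ages on both sides, so the age difference widens its spread and pushes its count toward 0. With 10 divisions the share cannot go under 0.1, so they are too few for a share under 0.05. The other divisions that part all 3 pairs of replicate numbers each mix the groups and also gave 0.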
